A study of Mus musculus with 144 samples.

How the data were processed

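Liver, endothelial and Kupffer cell RNA of 144 libraries was analysed from 4 deposited tables, 1 per sample type and feeding schedule, each with a column per library. Per the labels' protocols, total RNA was extracted with Trizol and a column kit and made into TruSeq RNA libraries. The submitters' processing notes name STAR, HOMER and the mm9 genome build, with no versions. Further settings are not given in the sources used here.

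The authors' liver tables hold expected counts per transcript: each deposited value is a multiple of 0.5, and 29.5% of values ad libitum and 31.9% under reverse-phase feeding were not whole. They were rounded to whole numbers before the tests. The deposited endothelial and Kupffer values are a signal after quantile normalisation, a step read from the values and not stated in the labels: all 24 columns of each table hold 1 set of sorted values. Their depth cannot be recovered, and 71.6% and 71.3% of their values were not whole. A count test had been planned for these tables and was replaced by limma on log2(value + 1). Quantile normalisation forces the same distribution on each library, so a change shared by most genes cannot be seen there.

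Each table has 34600 transcript rows. For each of 24421 gene symbols the transcript with the largest mean over all libraries, each scaled to its total, was kept, since rows share exons. Of these genes, 413 are listed at several genomic copies. Coordinates are those of the tables, on mm9. A RefSeq table on GRCm38 was used only to match transcript accessions (98.9% matched), and none of its coordinates is given. The 45S ribosomal transcript Rn45s took a median of 0.70% of counts ad libitum and up to 12.3% in 1 control ZT 22 library, and a median of 5.02% of the signal in endothelial libraries.

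Groups follow the labels: genotype, time and feeding schedule or cell type, 48 groups of 3 libraries. Libraries had 4.57e6 to 10.4e6 counts ad libitum and 13.1e6 to 26.2e6 under reverse-phase feeding, with 14442 to 15505 and 15325 to 16315 genes above 0. Reverse-phase tests therefore rest on more counts. Counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr over the groups, robust quasi-likelihood fit) and signal with limma 3.58.1 (trend, robust) on genes with a value of at least 10 in 3 libraries or more. Expression depended on genotype and, per genotype, on the cosine and sine of a 24-h period. The genotype effect is the knockout minus control difference of the fitted daily mean of log2 expression, called the daily mean below. It can exceed the log2 ratio of mean CPM where a gene swings more in controls. A rhythm is a test of the cosine and sine together, and a rhythm difference tests the difference of both terms between genotypes. The joint liver fit gives each schedule and genotype its own terms and was used only for differences that cancel a constant offset between the 2 tables. Other differences between the tables do not cancel and cannot be told apart from feeding. Benjamini-Hochberg adjusted p under 0.05 counts as called. The peak-to-trough range is that of the fitted curve. The SE of a log2 fold change is its size divided by the square root of F, and that of a peak time comes from the F of the rhythm test, both as approximations. Normalised CPM were taken after TMM scaling.

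Gene lists for pathways and cell type markers were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a table, and again with the correlation estimated. Lists, designs, the rule for named genes and these alternatives were fixed before the data were examined. The rule names the targeted genes; for the genotype effect up to 3 called members of each list with the largest fold change and the 5 largest called rises and falls with a mean log2 CPM of at least 1; for rhythms the clock list, up to 2 called members of each other list and the 5 smallest p outside the clock list; and the same for each interaction with feeding.

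The alternatives fixed beforehand were DESeq2 size factors, no filter on low genes, a mean of at least 1 CPM, DESeq2 1.42.0 (liver), the replicate number as a block, time as a factor, a second harmonic of 12 h for liver rhythms, a fold minimum of 1.5, and leaving out each library or, in the joint fit, each replicate number. Added after the data were seen were gene lists without each replicate number, other pseudocounts, the longest transcript per gene, marker scores and each library's slope of expression on transcript length as covariates, and fits without libraries that stand apart. There were 9 such libraries, beyond 3 median absolute deviations in that slope or in their spread around the group, or, in liver only, above 5% Rn45s: control ZT 16 and ZT 22 number 2 ad libitum, knockout ZT 10 number 3 under reverse-phase feeding, endothelial knockout ZT 22 numbers 2 and 3, and numbers 2 and 3 of both genotypes at ZT 4 in Kupffer cells. The hepatocyte share of an isolated-cell table is the ratio of its Alb share of all values to that of ad libitum liver. That share times the liver level gives the hepatocyte RNA expected for a gene.

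The models were tested on simulated data with 200 changed genes drawn at the real means and spreads. Each gene's noise was drawn independently, so deviations that many genes of a library share were absent. Recovery and false calls in the real tables may therefore differ from the values below. For the ad libitum genotype effect over 12569 genes, 88.0% of 1.5-fold and 98.0% of 2-fold changes were recovered with no false call. For the endothelial rhythm difference over 12523 genes, 34.0% of rhythms with a 2-fold and 62.0% with a 4-fold range were recovered, and 7.69% of calls were false. The genotype effect in Kupffer cells over 12270 genes recovered 72.0% of 1.5-fold and 80.0% of 2-fold changes. DESeq2, an alternative only, exceeded the bound of 15% false calls, which was set for all tests and limited to edgeR and limma after this was seen: for the reverse-phase control rhythm over 13838 genes 16.1% of its 93 calls were false, against 2.56% of 78 for edgeR. With no gene changed, 0.152% of its p-values for that test were under 0.001, against 0.0650% for edgeR. Analyses ran in R 4.3.3 and Python 3.11.15. The series' design text also names ATAC-seq and single-nucleus RNA-seq, for which no files were at hand. Single results of some genes are not reported here.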

Results

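RNA was sequenced from livers of male C57BL/6J mice on normal chow, from controls and from mice labelled as lacking both REV-ERB nuclear receptors in adult hepatocytes. REV-ERBα and REV-ERBβ, encoded by Nr1d1 and Nr1d2, are repressors within the circadian clock, the transcriptional loop that gives cells a daily rhythm. Whole liver was collected under ad libitum feeding and under reverse-phase feeding, in which mice eat in their rest phase. Each schedule had both genotypes at zeitgeber times (ZT, hours after lights on) 1, 4, 7, 10, 13, 16, 19 and 22, with 3 libraries per group and 48 per schedule. Endothelial cells, which line the liver sinusoids, and Kupffer cells, the resident macrophages, were isolated at ZT 4, 10, 16 and 22, giving 24 libraries each. The question, from the series title, is how the hepatocyte clock and feeding set daily gene expression in the cell types of the liver. Control and knockout are the labels' groups throughout. The deposited columns name them GFP and CRE, read here as the control vector and the recombinase. What was delivered thus differs between the groups along with the genotype, and these cannot be told apart. The labels do not say that each library came from its own animal, so p-values measure the spread between these libraries.

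Total counts per library, with 1 transcript per gene, ranged from 4.57e6 to 10.4e6 under ad libitum feeding and from 13.1e6 to 26.2e6 under reverse-phase feeding. The endothelial and Kupffer tables were deposited after quantile normalisation, so their depth is unknown. No 2 libraries of a group held identical values. In the liver tables the replicate pair with the closest counts still differed by 4.87 times the sampling noise (chi-square per degree of freedom).

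The targeted genes were measured first. Nr1d1 (NM_145434, mm9 chromosome 11, 98629246 to 98636691) had a mean of 45.9 ± 57.5 normalised CPM (SD, n = 24) in control and 73.2 ± 51.8 (SD, n = 24) in knockout liver under ad libitum feeding. Its daily mean of log2 expression rose in the libraries labelled knockout by 1.74 ± 0.15 (SE) ad libitum and by 1.83 ± 0.15 under reverse-phase feeding. The edgeR adjusted p was 1.03e-12 and 9.6e-14. Being a mean of logs, it gives the low control trough more weight than the mean CPM does. Nr1d2 (NM_011584, chromosome 14, 19036570 to 19071620) rose by 1.10 ± 0.10 and 0.80 ± 0.08, with adjusted p of 5.6e-13 and 1.3e-10. Ad libitum Nr1d1 had 3.05 ± 0.57 normalised CPM (SD, n = 3) in controls and 37.5 ± 2.89 in the knockout at ZT 22, 114 ± 31.6 and 149 ± 23.0 at ZT 4, and 158 ± 10.7 and 160 ± 13.9 at ZT 7. Nr1d2 had 64.5 ± 8.22 and 100 ± 11.2 at ZT 4, 94.4 ± 5.40 and 112 ± 5.28 at ZT 7, and 99.4 ± 8.98 and 93.2 ± 13.7 at ZT 10. Under reverse-phase feeding Nr1d1 was higher in the knockout at the control peak too, with 81.0 ± 9.69 and 114 ± 11.8 at ZT 19. The counts cover the whole transcript, including any exons outside the deleted part, and the deleted exons are not given in the sources used here. They therefore do not check the deletion. As a separate check on the labels, 2 of 96 liver libraries were nearer the other genotype's mean over 5 clock genes, both at ZT 1, where the 2 genotypes' means differed least. Since each library was compared with its own labelled group, this check sees single exchanged libraries and not an exchange of whole groups.

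Under ad libitum feeding the knockout liver held far more Loxl4 and Npas2 RNA and far less Mup17 and Saa1 RNA than the control. Loxl4, a lysyl oxidase of the extracellular matrix (NM_001164311, chromosome 19, 42666769 to 42687296), rose by 4.47 ± 0.15 (SE) in the daily mean of log2 expression. Its mean level was 10.3 ± 13.1 normalised CPM in controls and 112 ± 22.6 in the knockout (SD, n = 24 each). Npas2, the clock activator that can stand in for CLOCK (NM_008719, chromosome 1, 39251117 to 39420085), rose by 3.93 ± 0.18. 1700010I14Rik rose by 3.24 ± 0.17, and Cyp17a1, a steroid hydroxylase, by 2.99 ± 0.19. Mup17, a major urinary protein (NM_001200006, chromosome 4, 61252963 to 61256864), fell by 6.93 ± 0.55, from 215 ± 275 to 1.64 ± 1.03 normalised CPM, with the largest fold of any named gene and a wide spread among controls. Acot3, an acyl-CoA thioesterase, fell by 3.57 ± 0.41 and Saa1, an acute-phase protein, by 3.33 ± 0.36. Mup15 fell by 2.69 ± 0.42 and Saa2 by 2.68 ± 0.39. The Mup, Saa, Acot and Cyp2a families have near-identical members, so counts of single members are uncertain. Moxd1 rose by 3.02 ± 0.80, with 0 to 366 counts per knockout library, and under reverse-phase feeding its value was -0.91 ± 1.60 with adjusted p = 0.728.

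In all, 3428 of 12569 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test of the daily mean, 1703 higher and 1725 lower in the knockout. Of these, 279 rises and 242 falls were at least 1.5-fold. Under reverse-phase feeding 3709 of 13838 genes passed, 1754 higher and 1955 lower, with 364 rises and 347 falls of at least 1.5-fold. Among the 12524 genes tested under both schedules, 2252 were called in both, against 968 expected of independent lists, and 2249 of them changed in the same direction. The separate libraries of each schedule enter each test, so no controls are shared.

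Under reverse-phase feeding the leading rises were Loxl4 at 5.24 ± 0.10 (SE), the steroid hydroxylase Cyp2a4 at 5.06 ± 0.34, Npas2 at 3.89 ± 0.17, 1700010I14Rik at 3.81 ± 0.16 and D630024D03Rik at 3.58 ± 0.13 on the log2 scale. Mup17 fell by 3.44 ± 0.40 and Acot3 by 3.37 ± 0.31. The glutathione transferase Gsta1 fell by 3.28 ± 0.30, the maternally expressed noncoding RNA Meg3 by 3.10 ± 0.21 and the collagen Col27a1 by 3.09 ± 0.18. The highest edgeR adjusted p among these 10 genes was that of Mup17, at 3.3e-09.

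**Figure D1:**
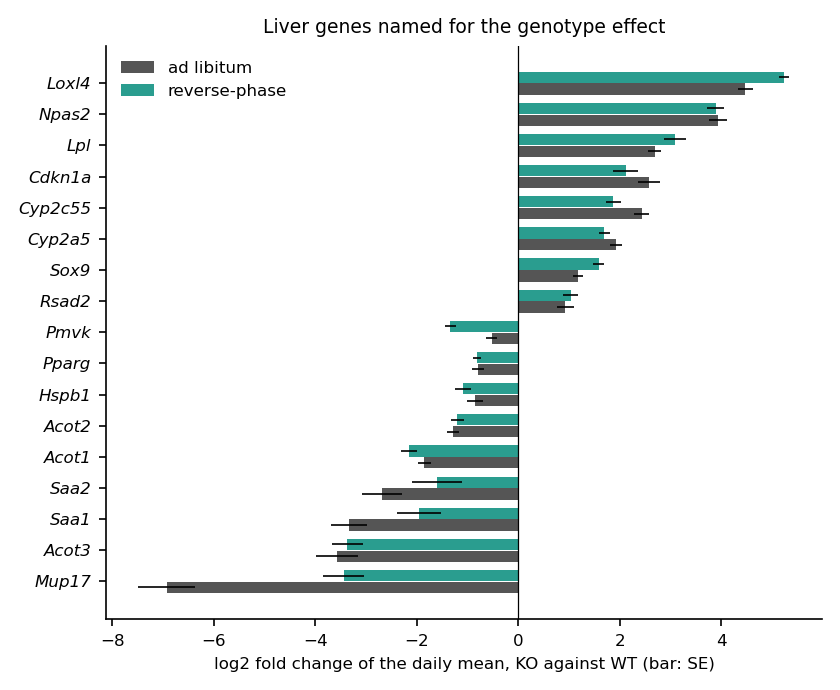
Log2 fold change of the daily mean, knockout against control, for a selection of the genes named for the genotype effect, without Cyp2a4 (horizontal axis; bars start at 0 and lines show the SE), under ad libitum (grey) and reverse-phase feeding (green). Of the genes shown, Loxl4 and Npas2 lie farthest to the right under both schedules, and Mup17 and Acot3 farthest to the left.

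Several fixed gene groups moved in knockout liver. Of the 23 measured genes of fatty acid oxidation and PPARA targets, 14 fell and 2 rose ad libitum (15 and 2 adjusted over the list alone), and 13 fell and 1 rose under reverse-phase feeding (14 and 2 adjusted over the list alone). Acot1, which frees fatty acids from coenzyme A, fell by 1.85 ± 0.12 and 2.15 ± 0.16 (SE, log2), and Acot2, its mitochondrial relative, by 1.28 ± 0.12 and 1.2 ± 0.13. Pdk4, a brake on glucose oxidation, rose by 1.01 ± 0.21 ad libitum. The list fell in limma's camera test with adjusted p of 1.66e-06 and 1.28e-06, and was not called with an estimated correlation (adjusted p = 0.252 and 0.198). Of 19 core clock genes 9 rose and 2 fell ad libitum (9 and 2 adjusted over the list alone), and 10 rose and 1 fell under reverse-phase feeding (11 and 2 adjusted over the list alone). Arntl, which encodes BMAL1, the partner of CLOCK, rose by 1.61 ± 0.12 ad libitum, and Bhlhe41, a clock repressor, by 1.94 ± 0.23 under reverse-phase feeding. The clock list was the only list of either liver table still called with an estimated correlation (adjusted p = 0.0107 and 0.00121).

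Genes of cholesterol synthesis fell widely under reverse-phase feeding. There, 19 of 22 fell and none rose (21 and 0 adjusted over the list alone), with camera adjusted p of 5.3e-13 and, with an estimated correlation, adjusted p = 0.171. Pmvk, a kinase of the mevalonate pathway, fell by 1.34 ± 0.11 (SE, log2), the farnesyl diphosphate synthase Fdps by 1.23 ± 0.15 and the sterol demethylase Cyp51 by 1.0 ± 0.13. Ad libitum 4 of 22 fell (2 adjusted over the list alone), among them Pmvk by 0.53 ± 0.12, and the list was not called (adjusted p = 0.212). Of 21 genes of de novo lipogenesis, 9 fell and 1 rose under reverse-phase feeding (10 and 1 adjusted over the list alone), with adjusted p = 0.0110 and, with an estimated correlation, adjusted p = 0.623. Pnpla3, a lipid droplet hydrolase, fell by 1.21 ± 0.25, the fatty acid synthase Fasn by 0.84 ± 0.19 and the desaturase Scd1 by 0.83 ± 0.16. Ad libitum the list was not called (adjusted p = 0.908), with 2 rises and 3 falls (2 and 3 adjusted over the list alone). Insig2, which holds back the sterol-regulated transcription factors, rose there by 0.80 ± 0.07.

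Interferon response genes rose, 13 of 19 ad libitum and 9 of 19 under reverse-phase feeding (13 and 12 adjusted over the list alone), with no fall. Rsad2, the antiviral protein viperin, rose by 0.93 ± 0.16 and 1.04 ± 0.15 (SE, log2) and Ifit1 by 0.68 ± 0.15 and 0.56 ± 0.13. The list's camera adjusted p was 6.87e-06 and 0.00140, and with an estimated correlation adjusted p = 0.345 and 0.703. Nuclear genes of oxidative phosphorylation rose by little: 40 of 89 rose and 2 fell ad libitum (41 and 2 adjusted over the list alone), and 29 of 90 rose and 3 fell under reverse-phase feeding (32 and 3 adjusted over the list alone). Their median log2 change was 0.11 and 0.08, with adjusted p of 1.3e-07 and 0.000822, and with an estimated correlation adjusted p = 0.498 and 0.837. Acute-phase and inflammation genes fell ad libitum, 7 of 12 with 1 rise (8 and 1 adjusted over the list alone), with adjusted p = 0.00171 and, with an estimated correlation, adjusted p = 0.345. Under reverse-phase feeding 7 of 14 fell and 2 rose (7 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.0562). Saa1 fell by 1.96 ± 0.43 there and the acid glycoprotein Orm2 by 1.19 ± 0.25. Extracellular matrix genes rose ad libitum, 7 of 10 with 1 fall (7 and 1 adjusted over the list alone), the collagen Col3a1 by 0.71 ± 0.17, with adjusted p = 0.0183 and, with an estimated correlation, adjusted p = 0.496. Under reverse-phase feeding the matrix list was not called (adjusted p = 0.0562). Cell cycle genes were called higher under reverse-phase feeding, with 4 of 18 risen (4 adjusted over the list alone), adjusted p = 0.0141 and, with an estimated correlation, adjusted p = 0.735. Cdkn1a, a member of that list, encodes the cell cycle inhibitor p21 and rose by 2.57 ± 0.22 and 2.11 ± 0.25.

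Markers of other liver cells moved too. Of 21 endothelial markers, 14 rose ad libitum and 8 under reverse-phase feeding (19 and 9 adjusted over the list alone), with a median log2 change of 0.26 and 0.17. Rspo3, a Wnt signal enhancer of the central vein endothelium, rose by 0.49 ± 0.09 and 0.33 ± 0.08 (SE). Of 11 stellate cell markers, 10 and 8 rose (10 and 9 adjusted over the list alone), Reln by 0.54 ± 0.08 and 0.46 ± 0.07. Camera adjusted p was 6.87e-06 and 0.00422 for endothelial markers (with an estimated correlation, adjusted p = 0.394 and 0.735), and 6.87e-06 and 0.000612 for stellate markers (with an estimated correlation, adjusted p = 0.190 and 0.171). None of 16 Kupffer markers was called (0 adjusted over the list alone), with Clec4f at -0.03 ± 0.07 and 0.01 ± 0.08. Hepatocyte markers were called higher ad libitum, with 9 of 13 risen and 2 fallen (9 and 2 adjusted over the list alone), adjusted p = 0.0415 and, with an estimated correlation, adjusted p = 0.496, and were not called under reverse-phase feeding (adjusted p = 0.565). Alb, the transcript of serum albumin, fell by 0.36 ± 0.05 and 0.42 ± 0.06. Sox9, the 1 called cholangiocyte marker, rose by 1.18 ± 0.10 and 1.59 ± 0.11, while that list was not called (adjusted p = 0.0627 and 0.0938).

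The lists of bile acid, glucose and glycogen, xenobiotic, heat shock, endoplasmic reticulum stress, MHC class II, immediate early, lipid handling and ribosomal protein genes were not called in either liver table, nor were those of neutrophil and monocyte or erythroid markers. The lymphocyte list, with 1 measured member ad libitum, was not called under reverse-phase feeding. Single members changed nonetheless. The fatty acid hydroxylase Cyp2c55 rose by 2.43 ± 0.14 and 1.87 ± 0.15 (SE, log2) and Cyp2a5, a coumarin hydroxylase, by 1.92 ± 0.12 and 1.70 ± 0.10. The lipoprotein lipase Lpl (NM_008509, chromosome 8, 71404454 to 71430831) rose by 2.69 ± 0.13 and 3.09 ± 0.21. Pparg, a nuclear receptor of fat storage, fell by 0.79 ± 0.11 and 0.81 ± 0.08, and the small heat shock protein Hspb1 fell by 0.84 ± 0.16 and 1.09 ± 0.15. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.10 ± 0.24 under reverse-phase feeding, and ad libitum its value was -0.31 ± 0.23 with adjusted p = 0.332. The sign of the median and that of the test differed for de novo lipogenesis, xenobiotic and endoplasmic reticulum stress genes ad libitum and for glucose and glycogen and immediate early genes under reverse-phase feeding. In the isolated cells the median or the mean differed in sign from the test for clock genes and stellate markers in endothelial cells, and for PPARA targets, bile acid genes, stellate and neutrophil and monocyte markers in Kupffer cells, none of them called.

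In control liver fed ad libitum, all 19 clock genes were rhythmic (19 adjusted over the list alone). Arntl (NM_007489, chromosome 7, 120350980 to 120457640) peaked at ZT 21.9 ± 0.25 h (SE) with an 18.9-fold range from peak to trough in the 24-h fit, Npas2 at ZT 23.3 ± 0.21 h and Nr1d1 at ZT 6.84 ± 0.20 h with a 68.9-fold range. In the knockout 15 of 19 remained rhythmic (16 adjusted over the list alone), and the rhythm itself differed between genotypes for 8 (13 adjusted over the list alone). Arntl stayed at a high level with a 1.39-fold range and was not called rhythmic (edgeR adjusted p = 0.17), and Npas2, with a 1.51-fold range, was called over the list alone and not over all genes (adjusted p = 0.053). Their tests of the genotype difference gave adjusted p of 8.0e-10 and 4.3e-14. Nfil3, a repressor of clock output genes, also differed (adjusted p = 2.8e-08), with a 3.75-fold range in controls and 1.28-fold in the knockout. Cry1 had a 1.83-fold range against 9.14-fold. Per2 peaked at ZT 14.9 ± 0.28 h in controls and at ZT 15.4 ± 0.39 h in the knockout, and Dbp at ZT 9.31 ± 0.27 h and ZT 8.91 ± 0.36 h. Neither passed the test of a difference (adjusted p = 0.23 for each).

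**Figure D2:**
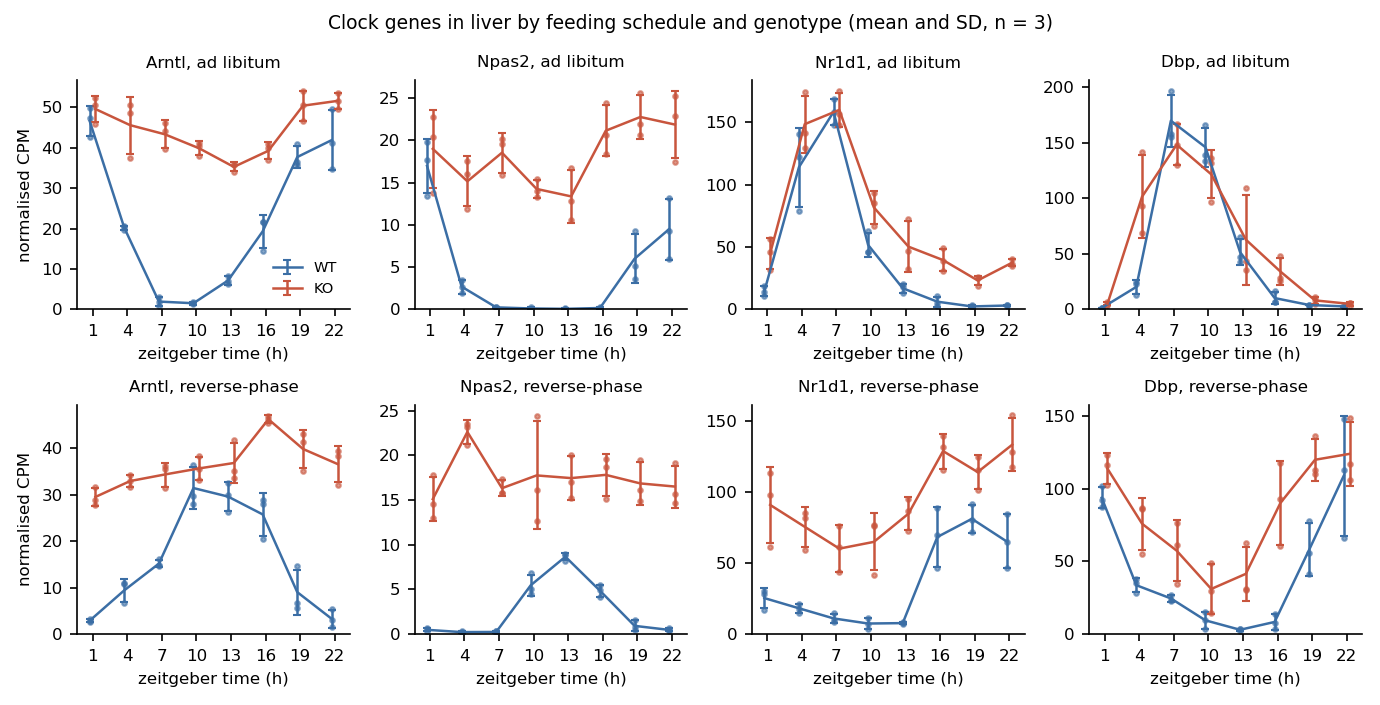
Normalised CPM of Arntl, Npas2, Nr1d1 and Dbp in liver against zeitgeber time (h), control (blue) and knockout (red), with means and SD of 3 libraries as lines and bars and libraries as points. The upper row is ad libitum and the lower row reverse-phase feeding. Arntl in knockout libraries stays between 34.0 and 54.0 ad libitum, and in control libraries it runs from 0.89 to 49.7.

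Over all genes, 6039 of 12569 were rhythmic in ad libitum controls and 5545 in the knockout, with 4060 called in both, and 423 differed in rhythm between genotypes. The smallest p outside the clock list was that of Clpx, a mitochondrial protease subunit (NM_011802, chromosome 9, 65142067 to 65178465), with a 6.53-fold range in controls, 1.29-fold in the knockout and adjusted p = 4.4e-18. Insig2 and Loxl4 were among those that followed. Insig2 went from a 4.93-fold to a 1.23-fold range and Loxl4 from 38.9-fold to 1.15-fold. Car14, a carbonic anhydrase, was called in both genotypes, peaking at ZT 22.7 ± 0.62 h in controls and ZT 13.4 ± 0.38 h in the knockout. In the lists, Srebf1, a driver of lipogenesis, had a 3.47-fold range in the knockout and 1.19-fold in controls (adjusted p of the difference = 0.0050). The fibrinogen gene Fga peaked at ZT 4.20 ± 0.51 h in controls and ZT 8.96 ± 0.51 h in the knockout, and Fgb changed likewise. Cdkn1a peaked at ZT 20.5 ± 0.48 h with a 17.1-fold range in controls and at ZT 12.7 ± 0.67 h with a 4.09-fold range in the knockout.

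Reverse-phase feeding turned the phase of the liver clock in both genotypes. In controls Arntl peaked at ZT 11.9 ± 0.24 h (SE), Nr1d1 at ZT 20.2 ± 0.33 h, Per2 at ZT 3.50 ± 0.37 h and Dbp at ZT 23.96 ± 0.34 h, and 17 of 19 clock genes were rhythmic (17 adjusted over the list alone). In the knockout 11 were (11 adjusted over the list alone), and 10 differed in rhythm between genotypes (15 adjusted over the list alone). Arntl had a 1.35-fold range in the knockout and Cry1 a 1.27-fold range, against 10.6-fold and 5.66-fold in controls. Over all genes 5698 of 13838 were rhythmic in controls and 5099 in the knockout, and 209 differed between genotypes. Clpx again had the smallest p outside the clock list (adjusted p = 7.7e-17), with Loxl4, the galectin-related Lgalsl, the stress-response gene Ndrg1 and the choline kinase Chka next. Between the schedules 112 genes were called for a rhythm difference in both, against 6.97 expected of independent lists. With time as a factor 133 genes were called for the rhythm difference under reverse-phase feeding, 471 with each library's dependence on transcript length as a covariate and 327 in DESeq2.

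Of the genes rhythmic under both schedules in both genotypes, 1732 in number, the median peak moved by 10.01 h in controls and by 9.77 h in the knockout, and 1592 and 1557 of them moved by over 6 h. In the joint fit of 96 libraries the rhythm differed between schedules for 7266 of 13566 genes in controls and 6708 in the knockout, including 19 and 16 of 19 clock genes (19 and 17 adjusted over the list alone). All 22 cholesterol synthesis genes were among the calls in each genotype (22 adjusted over the list alone). The effect of the knockout on the rhythm differed between schedules for 725 genes, among them 13 clock genes (15 adjusted over the list alone). This count was 413, 417 and 285 without all libraries numbered 1, 2 and 3, and the 6708 genes were 4411 without number 3. Levels were not compared between schedules, since each schedule is a separate table. For the same reason, differences between the tables beyond a constant offset, such as depth, cannot be told apart from feeding in these joint counts.

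The effect of the knockout on the daily mean differed between schedules for 28 genes. Here too, feeding cannot be told apart from other differences between the 2 tables. Hectd2, a ubiquitin ligase (NM_001163471, chromosome 19, 36629129 to 36695625), rose by 1.92 ± 0.11 (SE, log2) ad libitum and by 3.40 ± 0.12 under reverse-phase feeding, a difference of 1.49 ± 0.15 with edgeR adjusted p = 1.49e-11. 1500017E21Rik rose by 2.04 ± 0.11 and 3.48 ± 0.12, and Cyp2a4 by 2.56 ± 0.20 and 5.06 ± 0.34. Mbl2, which encodes a mannose-binding lectin, rose by 0.41 ± 0.08 ad libitum and fell by 0.24 ± 0.07 under reverse-phase feeding. The pseudogene Rdh18-ps fell by 1.04 ± 0.11 under reverse-phase feeding, and its ad libitum value was -0.13 ± 0.05 with adjusted p = 0.055. Among the lists, the difference was called for the lipogenesis gene Fads1 (-0.36 ± 0.08), for Pmvk (-0.81 ± 0.16) and for Fdps (-0.98 ± 0.22), each lower in the knockout by more under reverse-phase feeding. Of 22 cholesterol synthesis genes 2 were called over all genes and 16 adjusted over the list alone. The count of 28 was 54 with time as a factor, 100 with the length covariate and 68 in DESeq2, and it was 6 without all libraries numbered 2 and 18 without those numbered 3.

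In isolated endothelial cells the clock ran in both genotypes. Of 19 clock genes 14 were rhythmic in each (17 in controls and 16 in the knockout adjusted over the list alone), and none differed in rhythm between genotypes (0 adjusted over the list alone). Arntl had a 23.2-fold range with a peak at ZT 23.4 ± 0.41 h (SE) in controls and a 23.1-fold range with a peak at ZT 0.42 ± 0.41 h in the knockout. Nr1d1 peaked at ZT 8.15 ± 0.28 h and ZT 8.07 ± 0.34 h, and Dbp at ZT 9.23 ± 0.37 h and ZT 10.2 ± 0.43 h. In Kupffer cells 9 of 16 clock genes were rhythmic in each genotype (10 and 9 adjusted over the list alone), none with a difference (0 adjusted over the list alone). In simulated data with independent noise per gene, the endothelial difference test recovered 34% of rhythms with a 2-fold and 62% with a 4-fold range. The Kupffer test recovered 38% and 66%, so differences of such size may be missed. Arntl had a 3.99-fold range in controls and 3.55-fold in the knockout. Per2 peaked at ZT 18.0 ± 0.34 h and ZT 17.2 ± 0.31 h, and Cry1 at ZT 19.7 ± 0.32 h and ZT 18.6 ± 0.39 h. These values come from limma on log2(value + 1), a scale that understates the change of low genes.

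**Figure D3:**
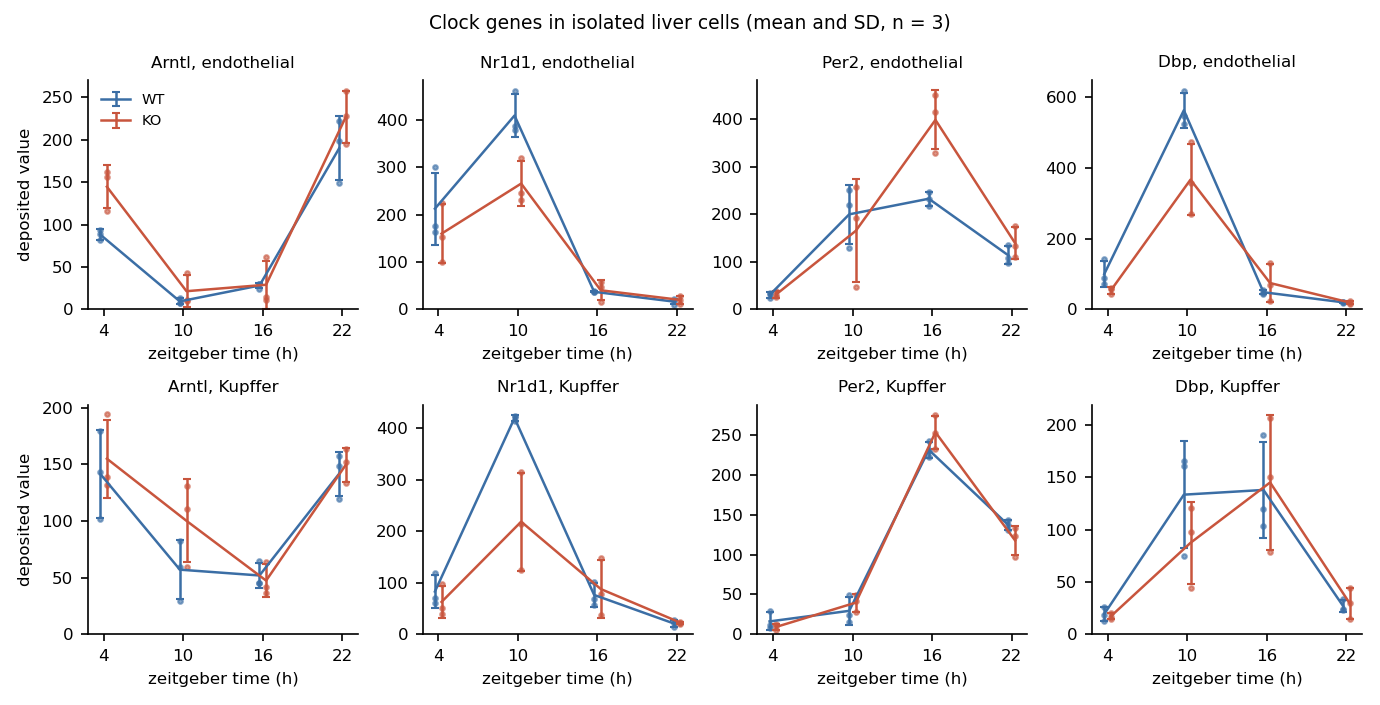
Deposited quantile-normalised value of Arntl, Nr1d1, Per2 and Dbp in isolated cells against zeitgeber time (h), control (blue) and knockout (red), with means and SD of 3 libraries as lines and bars and libraries as points. The upper row is endothelial and the lower row Kupffer cells. Arntl in endothelial controls runs from a mean of 9.38 at ZT 10 to 190 at ZT 22, and in the knockout from 21.4 to 227.

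Over all genes, 768 of 12523 genes were rhythmic in endothelial controls and 1653 in the knockout, with 240 in both, and 256 differed in rhythm between genotypes in limma. These included 8 of 73 ribosomal protein genes (26 adjusted over the list alone), such as Rps15 and Rps7, which peaked at ZT 17.8 ± 0.72 h and ZT 17.6 ± 0.82 h in the knockout and were not called in controls. Others were the cytochrome P450 reductase Por, the lipogenic regulator Srebf1, the vascular receptor Eng and the kinesin Kifc3, whose adjusted p was 0.030. The count was 43 with time as a factor, 62 with no filter on low genes, 5 with each library's dependence on transcript length as a covariate, 568 with hepatocyte markers as a covariate, and 121 without the knockout ZT 22 libraries 2 and 3, which stood apart from the rest. It was 0 without any 1 of 7 libraries (control ZT 10 numbers 2 and 3, control ZT 22 number 2, knockout ZT 10 numbers 1 and 3, knockout ZT 16 numbers 1 and 2) and 1328 without knockout ZT 22 number 1. The rhythm counts of 768 and 1653 moved as well, to 398 and 1035 with the length covariate, 221 and 1762 with Kupffer markers as a covariate, and 1267 and 1574 without the libraries that stood apart, and they ran from 248 to 1164 and from 733 to 2441 when single libraries were left out. Kupffer markers were partly rhythmic in these endothelial libraries: of 16, 1 was called in controls and 2 in the knockout (12 and 6 adjusted over the list alone). No gene of Kupffer cells was called for a rhythm difference between genotypes in limma. At an unadjusted p under 0.05 there were 279, fewer than the share of 0.05 of tested genes that no difference at all would give. They are thus no sign of hidden differences. A count below that share can also come from a test that is too strict, so it does not exclude them. In Kupffer cells 241 of 12270 genes were rhythmic in controls and 222 in the knockout, with 103 in both. Without libraries 2 and 3 of ZT 4 in both genotypes, which stood apart in their dependence on transcript length, 121 and 76 were called, and without single libraries the counts ran from 112 to 320 and from 57 to 310.

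The genotype effect on the daily mean was called for 4 endothelial and 3 Kupffer genes, with 1 to 7 and 2 to 7 called when single libraries were left out. Without ZT 22, 2 and 0 genes were called, 1 and 0 of them among these, and without the libraries that stood apart 2 and 3, with 2 and 1 among these. In endothelial cells Cyp17a1 rose by 3.07 ± 0.34 (SE, log2), 1500017E21Rik by 2.15 ± 0.36 and the glutathione transferase Gstm3 by 1.87 ± 0.32, and Mup17 fell by 2.41 ± 0.42. In Kupffer cells Cyp17a1 rose by 2.99 ± 0.35 and Gstm3 by 1.95 ± 0.36, and Mup17 fell by 2.80 ± 0.44. Mup17 lies under the expression minimum for named genes in both tables and was named after its values were seen. Each of these genes changed in the same direction in liver, and Gstm3 rose there by 2.14 ± 0.15 ad libitum. Hepatocyte transcripts were present in both preparations: Alb stood at 6.55% of its liver level on average in endothelial libraries (1.53 to 27.4%) and at 4.75% in Kupffer libraries (0.84 to 12%). For all 7 calls the RNA expected from that share exceeded 10% of the measured value, as it did for 23.2% of tested endothelial and 17.5% of tested Kupffer genes. With hepatocyte markers as a covariate in limma, 54 endothelial and 39 Kupffer genes were called, with the 4 and 3 genes among them.

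**Figure D4:**
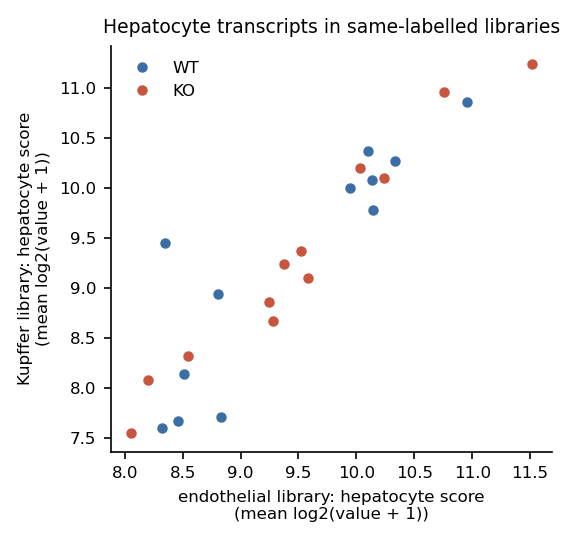
Mean log2(value + 1) of the hepatocyte markers in each Kupffer library (vertical axis) against the endothelial library of the same genotype, time and number (horizontal axis), 24 pairs, control (blue) and knockout (red). Libraries with more hepatocyte RNA in one cell type have more in the other.

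Gene lists moved in the isolated cells by the preset correlation alone. In endothelial cells camera called 11 lists, with no single member called in any of them. Higher were interferon response (adjusted p = 7.65e-08), glucose and glycogen (4.05e-05), de novo lipogenesis (0.0400) and xenobiotic genes (0.0400). Hepatocyte markers, which were not called (adjusted p = 0.260), had a median log2 change of 0.12, against 0.19, 0.06 and 0.06 for glucose and glycogen, lipogenesis and xenobiotic genes. Lower were ribosomal protein (4.44e-14), MHC class II (7.65e-08), oxidative phosphorylation (0.000321) and cell cycle genes (0.0260), with Kupffer (8.27e-08), neutrophil and monocyte (0.00349) and lymphocyte markers (0.0118). Adjusted over the list alone, 4 of 7 MHC class II genes fell, 2 of 13 xenobiotic genes rose and 1 of 21 lipogenesis genes rose. MHC class II genes are abundant in Kupffer and other immune cells, and their median log2 change was -0.50 where that of Kupffer markers was -0.28. With an estimated correlation none of the 11 was called, with adjusted p from 0.286 to 0.680. In Kupffer cells 4 lists were called: MHC class II lower (adjusted p = 6.07e-06), glucose and glycogen higher (0.0134), oxidative phosphorylation lower (0.0134) and ribosomal proteins lower (0.0377). Their adjusted p was 0.628 to 0.961 with an estimated correlation. Without all libraries numbered 1, 5 lists were called in endothelial and 1 in Kupffer cells, and the direction of the test turned for xenobiotic genes in endothelial cells and for oxidative phosphorylation and ribosomal proteins in Kupffer cells. No list of the other kinds was called in either cell type.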

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

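The tests of clock genes within Kupffer cells and of exchanged groups, and the fits with marker scores or transcript length as a covariate or without the libraries that stood apart, were chosen after the data were seen.

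These results stand here because the same contrast differed between groups in a test of the difference itself. The rhythm differed between genotypes for 423 genes in ad libitum liver, 209 in reverse-phase liver and 256 in endothelial cells. Between schedules the rhythm differed for 7266 genes in controls and 6708 in the knockout, the effect of the knockout on the daily mean for 28 and its effect on the rhythm for 725. For the daily mean the adjusted p of the difference was 1.49e-11 for Hectd2, 9.31e-11 for 1500017E21Rik, 2.96e-08 for Rdh18-ps, 1.73e-06 for Cyp2a4 and 4.36e-05 for Mbl2, in edgeR. For the effect of the knockout on the rhythm it was 3.16e-35 for Clpx, 3.87e-25 for Loxl4, 2.76e-22 for Lgalsl and 6e-18 for Mad2l2.

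Whether chance gives such counts was tested by reassigning genotypes within a time, or times within a genotype, in 40 splits per table and 30 of the joint liver fit, the real one included. Chance is argued against where only 1 split of a single table, the real one, gave as many genes. The smallest p such splits can give is 1 in 40, and it was not adjusted over the results. In ad libitum liver the genotype effect had 3428 genes against 0 in the highest other split, the rhythm 6039 against 12 in controls and 5545 against 42 in the knockout, and the rhythm difference 423 against 28. Under reverse-phase feeding these were 3709 against 0, 5698 against 39, 5099 against 8 and 209 against 1. In endothelial cells they were 4 against 0, 768 against 0, 1653 against 157 and 256 against 0. The counts of 4 and 256 ran from 1 to 7 and from 0 to 1328 without single libraries, so their sizes are uncertain. In Kupffer cells the rhythm had 241 against 0 in controls and 222 against 6 in the knockout. In the joint fit the effect of the knockout on the daily mean had 28 against 1, the rhythm by feeding 7266 against 2 in controls and 6708 against 197 in the knockout, and the effect of the knockout on the rhythm 725 against 0. Reassigning times removes every rhythm, and reassigning genotypes removes every knockout effect. The joint splits therefore do not ask whether a rhythm or effect was equal under both schedules. For these counts they decide nothing about a difference between schedules. Chance cannot be excluded for the count of 3 in the Kupffer genotype effect, since 2 of 40 splits gave as many and the highest other gave 7. The splits compare only how many genes were called. That these 3 genes changed in the same direction in liver is no part of this test. The Kupffer rhythm difference had 0 genes, so that 40 of 40 splits gave as many decides nothing.

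The 256 rhythm differences in endothelial cells could come from RNA of other cells or from the libraries' dependence on transcript length. A varying amount of hepatocyte or Kupffer RNA is argued against as the whole cause. With the hepatocyte or the Kupffer marker score as a covariate, 99.6% and 98.4% of the 256 genes stayed called. A covariate for the amount leaves rhythms of that RNA itself in place. For hepatocyte RNA, 55 of the 256 genes (21.5%) exceeded 10% expected hepatocyte RNA, against 23.2% of tested genes. On the rough scale of Alb, the 256 genes were thus no richer in such genes than the tested ones. The expected RNA rests on the mean hepatocyte share and on liver levels averaged over time. Library shares ran from 1.53 to 27.4%, so a mean under 10% does not settle rhythms of hepatocyte RNA. Rhythms of hepatocyte RNA stay open, above all for the genes over 10%, and those of Kupffer RNA stay open for all. Length bias between libraries stays open: 1.95% stayed called with the length slope as a covariate, although the adjusted p of Kifc3 and Rps15 rose only from 0.0296 to 0.0677. The group means of that slope were lower at ZT 10 and ZT 16 than at ZT 4 and ZT 22 in both genotypes, so such a covariate could also remove true rhythms. A difference in endothelial rhythms that follows the hepatocyte knockout stays open too and was not tested apart from this.

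The 24-h rhythms of Kupffer cells could come in part from the ZT 4 libraries, of which numbers 2 and 3 in both genotypes lay 4.69 to 6.33 median absolute deviations from the median length slope. Of the genes called in either genotype 32.4% stayed called without these 4 libraries, which leaves 1 library per genotype at ZT 4 and so also lowers the power. A varying amount of hepatocyte RNA is argued against as the whole cause by the 96.8% that stayed called with the hepatocyte marker score as a covariate. Rhythms of that RNA itself are not covered by this. Expected hepatocyte RNA exceeded 10% for 22 of 241 control and 18 of 222 knockout calls (9.13% and 8.11%), against 17.5% of tested genes. On the rough scale of Alb, the calls were thus no richer in such genes than the tested ones. Library shares ran from 0.84 to 12% and liver levels were averaged over time, so a mean under 10% does not settle such rhythms. They stay open, above all for the calls over 10%. A 24-h clock in these cells fits 9 of 16 measured clock genes called in both genotypes. The batch stays open for the rest of the calls.

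Higher Nr1d1 and Nr1d2 counts in liver labelled as lacking these genes could come from mixed-up labels or from reads of another gene copy. Single exchanged libraries are argued against, since 2 of 96 liver libraries lay nearer the other genotype's mean of 5 clock genes. An exchange of whole groups is argued against, since liver labelled knockout had the weaker clock: over 12 clock genes rhythmic in endothelial cells of both genotypes, without Nr1d1 and Nr1d2, the log2 range from peak to trough differed from that in liver labelled control by a median of -1.12 (quartiles -2.16 and -0.83) ad libitum and -1.86 (-2.49 and -1.14) under reverse-phase feeding. Each transcript is listed at 1 genomic copy, which argues against a second listed copy of the same transcript. Sequences were not compared, so reads from a similar sequence elsewhere stay open. Transcripts that lack the deleted exons and are no longer repressed by the missing receptors stay open as a biological explanation, which counts per transcript cannot test.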

How the results depend on the processing

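The length covariate, marker covariates, other transcripts and pseudocounts, fits without ZT 22, without libraries that stood apart or without hepatocyte-derived genes, and gene lists without a replicate number were chosen after the data were seen. Counts stayed within 1.5 times the reported ones under every alternative run except those named here, and the cause was not tested unless stated.

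A fold minimum of 1.5, which only removes calls, left 521, 3068 and 2708 genes for the ad libitum genotype effect and rhythms in controls and knockout. It left 711, 2707 and 2339 under reverse-phase feeding, 160 and 132 Kupffer rhythms, and 4007 and 3461 rhythms by feeding. Time as a factor gave 133 reverse-phase and 43 endothelial rhythm differences and 54 genotype effects by feeding. DESeq2, which cannot be applied to the quantile-normalised tables, gave 327 reverse-phase rhythm differences and 68 genotype effects by feeding. With no filter, where more genes are tested, there were 486 endothelial control rhythms, 62 endothelial rhythm differences and 125 Kupffer knockout rhythms. The length covariate gave 471 reverse-phase rhythm differences, 398, 1035 and 5 for endothelial rhythms in controls, in the knockout and their difference, and 100 genotype effects by feeding. The hepatocyte covariate gave 54 endothelial and 39 Kupffer genotype effects and 568 endothelial rhythm differences, and the Kupffer covariate 2 genotype effects and 221 control rhythms in endothelial cells. Without hepatocyte-derived genes, which include all the calls, 0 genotype effects remained in either cell type. Without ZT 22 there were 2 endothelial and 0 Kupffer genotype effects and 428 endothelial rhythm differences. Without the libraries that stood apart there were 2 genotype effects, 1267 control rhythms and 121 rhythm differences in endothelial cells, and 121 and 76 Kupffer rhythms, the latter pair also without the ZT 4 libraries 2 and 3 alone. Of 33 list calls 2 held with an estimated correlation.

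Leaving out 1 library at a time kept all liver counts within 1.5 times: 3258 to 3525, 5762 to 6111, 5220 to 5657 and 364 to 452 ad libitum for the genotype effect, the rhythms in controls and knockout and their difference, and 3538 to 3802, 5025 to 6518, 4613 to 5659 and 170 to 235 under reverse-phase feeding. Endothelial counts ran from 1 to 7, 248 to 1164, 733 to 2441 and 0 to 1328. The endothelial rhythm difference was 0 without control ZT 10 number 2 or 3, control ZT 22 number 2, knockout ZT 10 number 1 or 3 or knockout ZT 16 number 1 or 2. It was 145 and 99 without control ZT 4 numbers 2 and 3, 37 and 24 without control ZT 16 numbers 1 and 2, 32 and 26 without control ZT 22 numbers 1 and 3, 157, 606 and 51 without knockout ZT 4 numbers 1, 2 and 3, and 1328, 494 and 120 without knockout ZT 22 numbers 1, 2 and 3. The control rhythm count was 335 without control ZT 4 number 2, 267 and 248 without ZT 10 numbers 2 and 3, 392 and 479 without ZT 16 numbers 1 and 2, 366 and 339 without ZT 22 numbers 1 and 3, and 1164 without knockout ZT 22 number 3. The knockout rhythm count was 964 without knockout ZT 4 number 3, 980 and 833 without ZT 10 numbers 1 and 3, and 733 and 865 without ZT 16 numbers 1 and 2. The endothelial genotype effect was 1 without control ZT 10 number 2 or knockout ZT 4 number 2, ZT 10 number 1 or ZT 16 number 3, 2 without control ZT 16 number 3 or ZT 22 number 1 or 3, and 7 without knockout ZT 22 number 2 or 3. Kupffer counts ran from 2 to 7, 112 to 320, 57 to 310 and 0 to 0. They left the 1.5-fold range at 7 genotype effects without control ZT 10 number 3, at 112, 128 and 126 control rhythms without control ZT 4 number 2 and ZT 16 numbers 1 and 3, and at 126, 121, 67, 91 and 57 knockout rhythms without knockout ZT 4 number 3, ZT 10 number 3 and ZT 16 numbers 1, 2 and 3. In the joint fit, where leaving out a number removes 1 in 3 libraries, counts ran from 6 to 23, 5384 to 6135, 4411 to 5459 and 285 to 417, and list calls over all tables from 24 to 40.

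Of 23810 values for named genes under alternatives 23069 kept their side of the threshold and direction, 632 lost the call, 94 gained it and 15 changed sign. All sign changes were genotype effects by feeding of clock genes, none of them called: Arntl at -0.14 with time as a factor, -0.00986 in DESeq2, and -0.00870, 0.0814 and -0.0312 without numbers 1, 2 and 3; Bhlhe40 at -0.0191 with time as a factor, -0.0204 without libraries that stood apart, and 0.199, -0.0123 and -0.0919 without numbers 1, 2 and 3; Npas2 at 0.0284 and Ciart at 0.0545 with the length covariate, at 0.0966 and 0.264 without number 1, and at their lowest of -0.237 and -0.332 without number 2 and number 3; and Nr1d1 at -0.111, Rora at 0.0482 and Hlf at -0.0390 without number 2, against 0.369, -0.138 and 0.176 without number 1. Without number 1, xenobiotic metabolism in endothelial cells (adjusted p = 0.858) and oxidative phosphorylation (0.610) and cytosolic ribosomal proteins (0.475) in Kupffer cells changed direction in camera and were no longer called, while their lowest adjusted p, without number 3, was 0.000190, 6.59e-05 and 0.000558.

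Control and knockout libraries with the same number were not treated as paired, since the labels give only a number. Deviations correlated above 0.1 in 3 of 24 pairs ad libitum, 6 of 24 under reverse-phase feeding, 1 of 12 endothelial and 4 of 12 Kupffer pairs. In these sets 9, 8, 5 and 5 libraries correlated best with their own number. The highest correlation was 0.419, in a Kupffer pair, so pairing by number is not excluded. With the replicate block the endothelial rhythm difference was 144, and other counts stayed within 1.5 times. Reverse-phase libraries held more counts than ad libitum ones, which limits comparisons of how many genes were called, and the depth of the isolated-cell tables is unknown.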

Other observations

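The tests of shared preparations and of hepatocyte RNA behind the genotype calls, the genes common to the cell types and the interferon rhythms were chosen after the data were seen.

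Across control and knockout endothelial and Kupffer cells, 24 genes had a 24-h rhythm in all of the sets. Besides 9 clock genes they include Plin2, a coat protein of lipid droplets, which peaked at ZT 6.46 and ZT 9.25 in control and knockout endothelial cells and at ZT 5.29 and ZT 6.66 in Kupffer cells. Calr, a calcium-binding chaperone of the endoplasmic reticulum, peaked at ZT 20.3 and ZT 20.1 in endothelial and ZT 21.5 and ZT 22.2 in Kupffer cells, and at ZT 20.4 in ad libitum control liver and ZT 11.1 under reverse-phase feeding. Limma's adjusted p for these rhythms ran up to 0.0455, that of Calr in endothelial controls. With the length covariate 23 genes were called in all of the sets, 19 of them among the 24. Plin2 stayed there and Calr did not. There were 17 genes without the libraries that stood apart, 13 of them among the 24. Leaving out single libraries gave 14 to 26 genes, with at least 14 of the 24 among them. In these 48 fits Plin2 stayed in 47 and Calr in 14. Without the libraries that stood apart neither Plin2 nor Calr remained.

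Interferon response genes were called rhythmic for 6 of 19 members in ad libitum controls and 17 in the knockout (5 and 17 adjusted over the list alone), while the difference in rhythm was called for 2 (4 adjusted over the list alone). Isg15, a ubiquitin-like modifier, had a 1.92-fold range in controls and 3.05-fold in the knockout, where it peaked at ZT 1.77 ± 0.52 h (SE). Under reverse-phase feeding 4 and 16 members were called (3 and 17 adjusted over the list alone) and the difference for 0 (7 adjusted over the list alone), with Isg15 in the knockout peaking at ZT 8.23 ± 0.49 h.

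Endothelial and Kupffer libraries with the same label may come from the same animals or preparations. Their hepatocyte marker scores deviated together from the group means over 24 pairs, with Pearson's r = 0.942 and Spearman's rho = 0.923, each with a permutation p of 1e-05, the smallest that 100000 resamples can give, and r = 0.925 without the 2 farthest pairs. Over all genes, deviations correlated above 0.1 in 22 of 24 pairs. The labels name no animals, so endothelial and Kupffer results are not taken as independent of each other.

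A candidate explanation for the genotype effects in isolated cells is RNA from hepatocytes, since 7 of 7 calls exceeded 10% expected hepatocyte RNA and moved as in ad libitum liver. The share of tested genes above 10% was 23.2% in endothelial and 17.5% in Kupffer cells. The expected RNA exceeded the measured value in 5 of the 7, so the Alb share is a rough scale. All 7 stayed called with the hepatocyte markers as a covariate, among 54 and 39 genes, which argues against a varying amount of hepatocyte RNA as the whole cause and leaves a genotype effect within that RNA open.

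The knockout was predicted to let clock-independent genes follow feeding further than in controls. Among 1732 genes rhythmic in both genotypes under both schedules, the median peak shift was 9.77 h in the knockout and 10.01 h in controls, a difference of -0.25 h, and among the 9 clock genes of this set it was 10.9 h and 10.3 h. The rule fixed beforehand asked for a larger median shift in the knockout over the 1732 genes. The median was not larger, so by that rule the result went against the hypothesis. The size of a shift ends at 12 h, and the upper quartile was 11.0 h in controls, which left little room for many genes. This limit was no part of the rule. The genes were not divided by clock dependence, and a larger shift in part of them stays open.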
